A study of Homo sapiens with 27 samples.

How the data were processed

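Messenger RNA of MCF7 cells was sequenced in 27 libraries, 3 for each of 9 groups given by background (WT, 20 µM J14, or a line labelled as overexpressing SRXN1) and treatment (PBS, 50 µM or 75 µM H2O2), 5 h after treatment. Groups were taken from the labels, and every column of the tables mapped to a sample. The submitters' notes name HISAT2, featureCounts, DESeq2 1.36.0 and the build hg38 without stating what each was used for, and state neither the annotation nor the strand setting of the counting, so overlapping genes on opposite strands may share counts. The deposited count table holds unnormalised counts per Entrez gene for 19328 genes, each with a total of at least 10. The authors' second table holds deposited TPM values (scaled to a fixed sum per library), after division by a gene length that is not stated. The 5 deposited tables of comparisons hold, per the file headers, the mean signal of normalised counts, the log2 fold change with its standard error, a score (the fold change over its error), and raw and adjusted p-values. No adjusted p was missing in them, and 1 table repeats the comparison of J14 with the SRXN1 line with the sign turned, so the other 4 were used.

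Symbols came from the deposited tables for 16489 genes and from a RefSeq table for 2515, and 324 genes had none. Counts were tested with edgeR 4.0.16 in R 4.3.3: the default filter on low counts (filterByExpr) left 15486 genes, TMM factors scaled the libraries, and a robust quasi-likelihood fit had 1 coefficient per group over all 27 libraries. The 16 comparisons were the 2 doses against PBS and against each other in each background, J14 against the SRXN1 line at 50 µM, each background against WT in PBS, and the differences between the responses of a background and of WT (interaction terms). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. With 3 libraries against 3, a permutation test of a single gene cannot give a p below 0.1, so p-values rest on the model fitted across all genes. Log2 CPM values used a prior count of 2.

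Gene lists (20, of 375 entries, 344 of them in the table) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists within a comparison, and with an estimated correlation and with fry as alternatives. The 13 mitochondrially encoded mRNAs had no place in the table, so 19 lists were tested. Their names and members, the comparisons, the tests, the rule for named genes and the other settings to try were fixed before the data were examined. By that rule SRXN1 came first. For each comparison it then took the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, leaving out names of the types LOC, LINC, antisense, MIR, SNOR and clones. Except for the differences of responses, these genes also needed all libraries of one group above all of the other. It added up to 4 members per list with the smallest p, and 31 genes fixed in advance. The text names fewer. Genes that changed their call under several settings were left out of the text where they were not needed.

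The settings chosen in advance were DESeq2-type factors (RLE) in edgeR, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), the replicate number as a block, only the compared groups in the fit, DESeq2 1.42.0, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, log2(TPM + 1) without that filter, an added threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. After the data were seen, 3 were added: a GC correction, which puts each library's deviation smoothed against transcript GC content into the offsets (96.2% of tested genes had a GC value), the removal of J14 PBS replicate 3 and WT PBS replicate 1 together, and the differences of the dose step between a background and WT. Replicate numbers gave little sign of pairing the samples. Each library's deviation from its group mean was correlated with those of libraries in other groups. The average was highest for its own replicate number in 40.7% of libraries, where chance gives 1 in 3.

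Library totals ran from 17111996 to 24212520 counts, and the 10 most abundant genes took 4.75 to 5.38% of them. A floor of 3 counts per library was used for genes with no or few counts, and it covers counting error only. No 2 libraries of a group were copies of each other: the chi-square per degree of freedom ran from 3.71 to 57.5 over 27 pairs. The procedure was tested on simulated data: of genes changed by 0.5, 1 and 2 log2 units, 54.5%, 86.6% and 100% were called between 2 groups, and 27.3%, 70.1% and 98.5% in a difference of responses. The simulation changed few genes, all with a mean log2 CPM above 1. It gave all groups the same spread and held no trend with GC content or transcript length. These shares thus do not describe genes with low counts or the more variable J14 PBS group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.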

Results

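Gene expression was measured by RNA sequencing in MCF7 cells, an estrogen receptor-positive breast cancer line, 5 h after exposure to hydrogen peroxide (H2O2) or to phosphate-buffered saline (PBS). The 27 libraries formed 9 groups of 3. The backgrounds were cells without a sulfiredoxin perturbation (WT), cells with 20 µM J14, and a line carrying a construct with human SRXN1 under a PGK promoter. Each was given PBS, 50 µM or 75 µM H2O2. SRXN1 encodes sulfiredoxin, which reduces hyperoxidised peroxiredoxins, and the submitters describe J14 as an inhibitor of sulfiredoxin. The design asks how the response to H2O2 depends on its dose and on sulfiredoxin. Counts per library summed to between 17111996 and 24212520. Of 19328 genes in the table, 15486 were tested. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are log2 values ± SE with n = 3 per group. The SE comes from the fit of all 27 libraries, in which the groups share an estimate of each gene's spread. A gene is said to rise or fall where its Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test was below 0.05. Each gene named below as risen or fallen between 2 groups had all libraries of one group above all of the other. Chance gives this for 10% of unselected genes. The naming rule required it of the largest rises and falls, so it is no separate support for the named genes. Beside a list's count of risen and fallen genes, the count adjusted over the list alone is given where it differed. Lists were called by camera with a preset correlation between genes, and those described also passed with an estimated correlation unless its p is given. Further lists called with the preset correlation only are left out. There were 1 for the SRXN1 line at 50 µM, 3 for J14 at 75 µM, 3, 5 and 2 for the dose steps in WT, J14 and the SRXN1 line, 1 each for J14 against that line and for each background in PBS. For the differences of responses from WT there were 2 at 50 and 2 at 75 µM with J14, and 3 at 50 and 4 at 75 µM in the SRXN1 line. In the difference with J14 at 50 µM, 7 lists passed with both correlations, and not all of these are described. Mitochondrially encoded genes were not in the table.

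Libraries of the J14 PBS group differed from each other more than those of other groups, mainly replicate 3 from the others. The biological coefficient of variation was 0.23 there and between 0.064 and 0.111 in the other 8 groups. Since the fit shares its estimate of the spread across groups, errors and p-values of comparisons with J14 PBS may be too small. The deviation of a library from its group mean was correlated with transcript GC content at -0.796 in J14 PBS replicate 3 and -0.476 in WT PBS replicate 1. These are correlations across genes, which are not independent replicates. Under the deposited TPM values the median of all genes lay at -0.112 for WT at 50 µM, -0.183 for J14 at 50 µM, -0.163 for WT at 75 µM and -0.168 for J14 at 75 µM, where under the main scaling it lay near 0 (0.02 to 0.03). The same scaling put it at -0.104 for J14 against the SRXN1 line at 50 µM and at 0.103 for the difference of responses between that line and WT at 50 µM. All fold changes below are relative to the main scaling.

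SRXN1 (Entrez gene 140809, chromosome 20, 646615 to 653200 in GRCh38) averaged 177 ± 8.21 CPM (library-scaled counts, mean ± SD, n = 3) in WT cells in PBS, 247 ± 3.14 at 50 µM and 190 ± 1.93 at 75 µM H2O2. With J14 the means were 188 ± 1.33 in PBS, 216 ± 8.93 at 50 µM and 197 ± 12.7 at 75 µM. The line labelled as overexpressing SRXN1, called the SRXN1 line below, had 197 ± 5.38 in PBS, 395 ± 6.75 at 50 µM and 299 ± 12.1 at 75 µM. In PBS the line thus stood 0.15 ± 0.05 log2 above WT (adjusted p = 0.053, higher in 3 of 3 libraries), which was not called. This small difference was called without WT PBS replicate 2 (0.20, adjusted p = 0.0283) and by DESeq2 (0.16, adjusted p = 0.0234). It was also called with RLE factors (adjusted p = 0.0383), a stricter filter (0.0368), a GC correction (0.0241) and 1 library fewer in WT PBS and J14 PBS (0.046). The files do not tell whether transcripts of the construct were counted, and the group is named by its label throughout.

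SRXN1 rose at 50 µM by 0.48 ± 0.05 in WT and by 1.01 ± 0.05 in the SRXN1 line, and at 75 µM by 0.60 ± 0.05 in the SRXN1 line. In WT at 75 µM its fold change was 0.10 ± 0.05 (adjusted p = 0.162). With J14 it was 0.20 ± 0.05 at 50 µM (adjusted p = 0.00263) and 0.07 ± 0.05 at 75 µM (adjusted p = 0.303), and both turned negative under the deposited TPM values, to -0.04 (adjusted p = 0.525) and to -0.15, a called fall (adjusted p = 0.00857). The call in J14 at 50 µM also ended with a GC correction (0.08, adjusted p = 0.187) and with the 2 groups alone in the fit (0.18, adjusted p = 0.11).

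**Figure D1:**
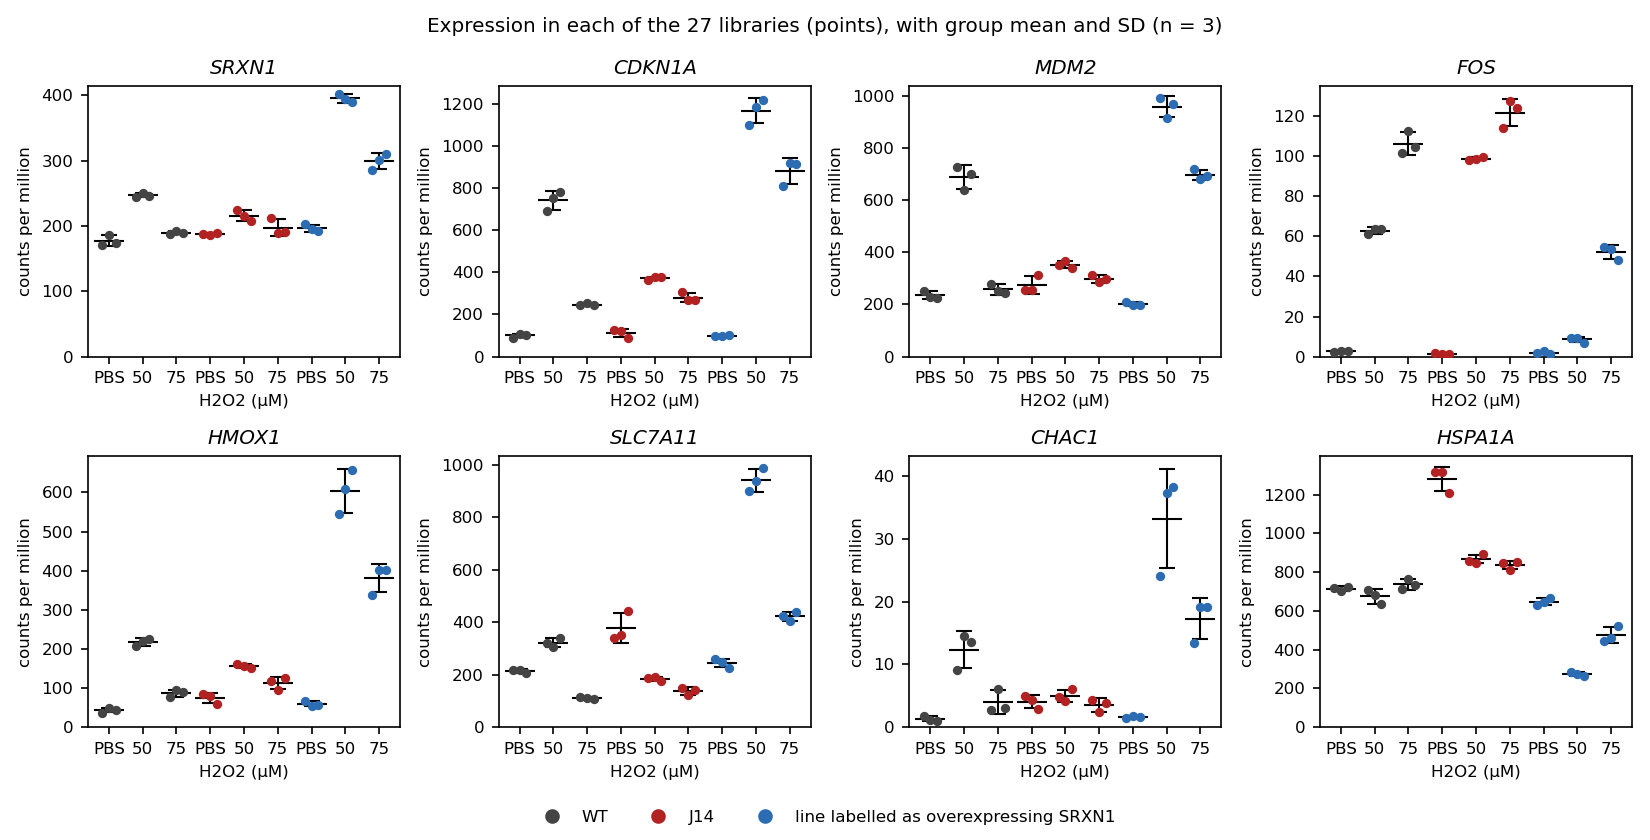
CPM (y axis) of 8 genes in each library (points) by H2O2 dose (x axis, µM) in WT (grey), J14 (red) and the line labelled as overexpressing SRXN1 (blue), with the mean and SD of each group (bars, n = 3). SRXN1 in PBS averaged 177, 188 and 197 in the 3 backgrounds, and CDKN1A was highest at 50 µM in the SRXN1 line, at 1166 on average.

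In WT cells at 50 µM, immediate early transcription factors and p53 targets rose. FOS (4.60 ± 0.13), FOSB (5.05 ± 0.27), EGR4 (5.49 ± 0.61), EGR1 (3.47 ± 0.11) and JUN (1.97 ± 0.07), transcription factors induced within minutes of a stimulus, all rose. So did CDKN1A (2.88 ± 0.09), the p21 cell cycle inhibitor, MDM2 (1.55 ± 0.07), which limits p53, the apoptosis gene BBC3 (3.75 ± 0.36), GADD45A (3.58 ± 0.11), BTG2 (2.64 ± 0.08) and the secreted factor GDF15 (1.63 ± 0.18). ATF3 (4.97 ± 0.15), DDIT3 (2.12 ± 0.17), CHAC1 (3.25 ± 0.32), which degrades glutathione, and SESN2 (2.56 ± 0.09), all genes of the ATF4 stress response, rose as well. The fallers with the largest changes included the thyroid hormone deiodinase DIO2 (-2.28 ± 0.31), the zinc finger gene ZNF708 (-1.67 ± 0.31), the DNA demethylase TET1 (-1.51 ± 0.35) and AXIN2 (-1.47 ± 0.20), a target and inhibitor of Wnt signalling.

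Of 30 measured p53 targets, 28 rose and 0 fell at 50 µM in WT, with a median of 1.02 (camera, adjusted p = 1e-73). Of 25 immediate early genes 23 rose and 0 fell (24 adjusted over the list alone), with a median of 1.46 (adjusted p = 3.14e-101). Of 22 genes of the integrated stress response 17 rose and 0 fell, with a median of 0.64 (adjusted p = 1.97e-37). Among 25 NRF2 targets, the antioxidant programme, 17 rose (18 adjusted over the list alone) and 1 fell, with a median of 0.26 (adjusted p = 6.56e-08). Heme oxygenase HMOX1 rose by 2.32 ± 0.13, OSGIN1 by 1.01 ± 0.22, the glutathione synthesis gene GCLC by 0.64 ± 0.08 and the cystine transporter SLC7A11 by 0.59 ± 0.08, while the drug transporter ABCC3 fell by 0.58 ± 0.07. All 4 measured genes of metallothioneins and zinc export rose (adjusted p = 1.08e-15). Among them MT1F, which shares reads with close paralogs, rose by 2.82 ± 0.22 and the zinc exporter SLC30A1 by 1.93 ± 0.10. Of 15 NF-kB targets 8 rose and 0 fell (10 adjusted over the list alone; adjusted p = 4.9e-13). They included the chemokine CXCL8 (4.90 ± 0.61), TNFAIP3 (3.03 ± 0.12) and NFKBIA (1.01 ± 0.06). Of 13 hypoxia targets 9 rose and 0 fell (10 adjusted over the list alone; adjusted p = 1.25e-17), with ADM at 4.91 ± 0.26 and VEGFA at 1.04 ± 0.07. Of 21 FOXO targets 11 rose, such as CITED2 (1.09 ± 0.09), and 2 fell (adjusted p = 7.96e-09).

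Ribosomal protein genes, many of which share reads with processed pseudogenes, rose in 23 of 24 cases (24 adjusted over the list alone), with a median of 0.33 (adjusted p = 1.75e-10) and RPLP0 at 0.36 ± 0.04. Of 5 classes of genes by transcript length, the shortest had a median of 0.21 as a whole. Relative to the trend of all genes with transcript length, the median of the ribosomal protein genes was 0.15. Length was that of the longest annotated transcript of a gene, with a median of 1917 nt for these genes. Genes expressed as shorter forms are set against the trend at the wrong length, so such values do not show a rise beyond it. Of 19 peroxide and thioredoxin enzymes 12 rose and 0 fell (14 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.000526, but adjusted p = 0.0629 with an estimated correlation). PRDX1, a peroxiredoxin, rose by 0.32 ± 0.05, and FTH1, the ferritin heavy chain with many pseudogene copies, by 0.42 ± 0.06. Cholesterol synthesis genes fell in 8 of 15 cases, with HMGCR at -0.49 ± 0.07 (adjusted p = 0.00343, but adjusted p = 0.0919 with an estimated correlation). Of 18 G2/M genes 6 fell (7 adjusted over the list alone), such as CENPF (-0.67 ± 0.09), and 1 rose (adjusted p = 0.0268, but adjusted p = 0.43 with an estimated correlation). It was 0.0672 without WT PBS replicate 1 and 0.0882 with a GC correction.

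The other lists were not called at 50 µM in WT. Heat shock genes had 2 risen and 3 fallen of 16 (adjusted p = 0.599). Unfolded protein response genes had 4 risen and 3 fallen of 15 (4 and 4 adjusted over the list alone; adjusted p = 0.519), with a median of -0.02 but an upward test. G1/S and DNA replication genes had 2 risen and 6 fallen of 20 (7 fallen adjusted over the list alone; adjusted p = 0.202). Estrogen response genes had 3 and 4 of 17 (3 and 5 adjusted over the list alone; adjusted p = 0.357). Luminal identity genes had 3 risen and 5 fallen of 14 (4 and 5 adjusted over the list alone; adjusted p = 0.269), with a median of 0.02, or -0.11 under TPM, and a downward test. XBP1 was among the fallen, at -0.53 ± 0.05. Interferon response genes had 1 risen and 1 fallen of 11 (3 and 2 adjusted over the list alone; adjusted p = 0.507). Markers of basal, stromal and blood cells had 0 risen and 1 fallen of 6, with a median of -0.98 that turned to 0.15 under TPM (adjusted p = 0.506). In all, 1880 genes rose and 2219 fell in WT at 50 µM, and 925 rose and 3634 fell with the deposited TPM values.

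**Figure D2:**
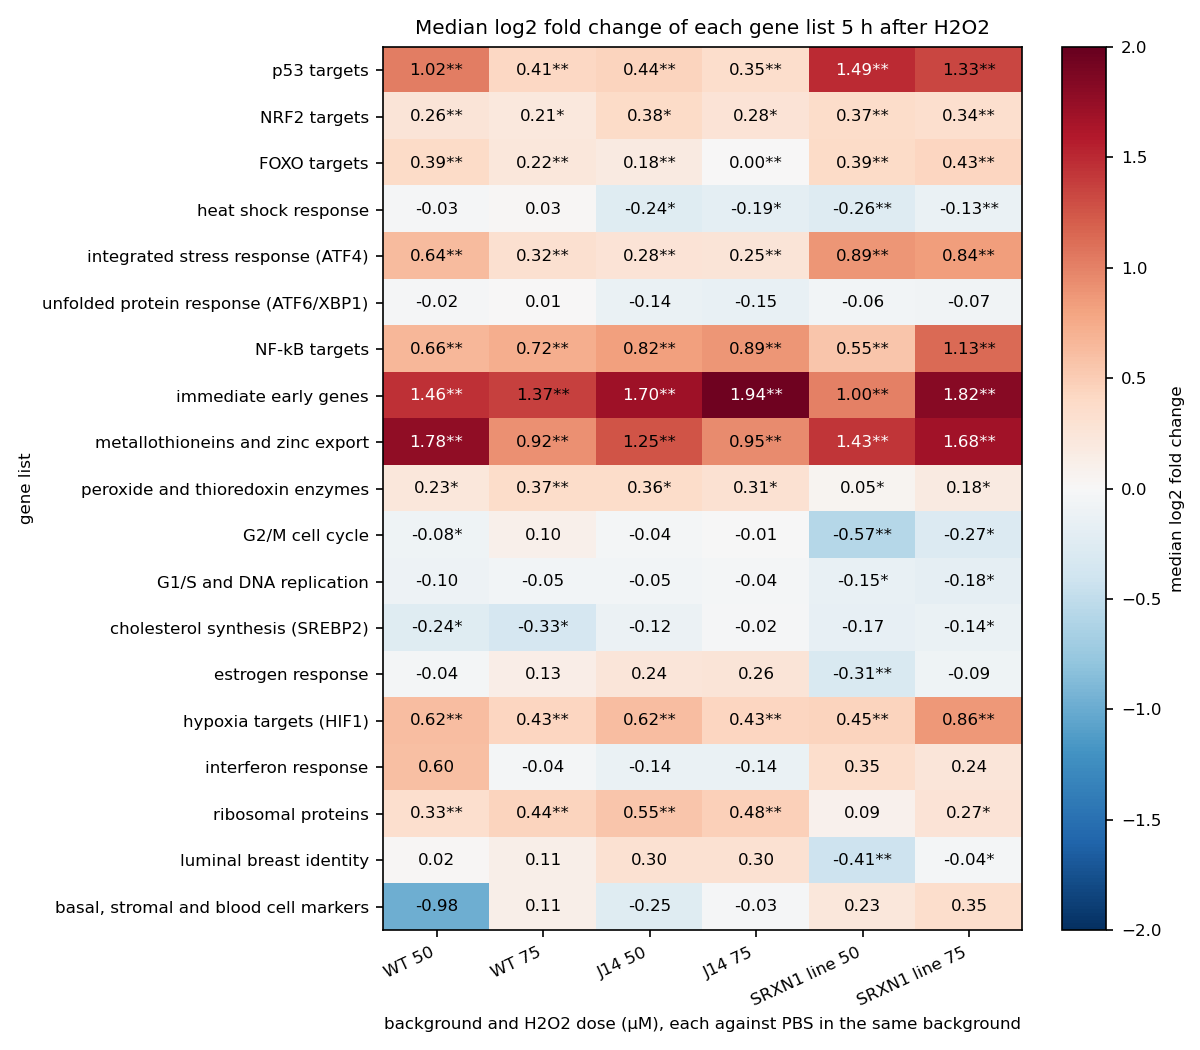
Median log2 fold change against PBS (colour and number) of each gene list (y axis) by background and H2O2 dose (x axis, µM), with 2 asterisks where camera called the list with the preset and with an estimated correlation, and 1 where only with the preset one. The median of the p53 targets was 1.02 in WT at 50 µM, 0.41 in WT at 75 µM and 1.33 in the SRXN1 line at 75 µM, and the FOXO medians of J14 turned negative under TPM (-0.14 at 50 µM and -0.17 at 75 µM).

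In WT cells at 75 µM, immediate early genes and the chemokine gene CXCL8 were again far above PBS, with FOS at 5.36 ± 0.13, EGR4 at 6.31 ± 0.59, CXCL8 at 5.63 ± 0.59 and ATF3 at 4.33 ± 0.14. The p53 targets CDKN1A (1.29 ± 0.09), BTG2 (1.52 ± 0.08) and GDF15 (0.72 ± 0.17) rose, and MDM2 stood at 0.13 ± 0.07 (adjusted p = 0.126; 0.25 with a GC correction, adjusted p = 1.07e-05, and -0.07 with TPM, adjusted p = 0.56). HMOX1 rose by 0.99 ± 0.13 while SLC7A11 fell by 0.96 ± 0.08. ADM (5.35 ± 0.25) and DDIT4 (2.90 ± 0.15), genes induced in hypoxia, rose too. HEG1 (-2.14 ± 0.25), NAV2 (-1.82 ± 0.22), the growth factor receptor EGFR (-1.81 ± 0.18) and ZNF708 (-2.07 ± 0.32) were among the largest falls.

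At this dose 18 p53 targets rose and 1 fell, with a median of 0.41 (camera, adjusted p = 3.68e-08). Immediate early genes had 24 risen and 1 fallen of 25 (median 1.37, adjusted p = 1.24e-84). The integrated stress response had 14 risen (15 adjusted over the list alone) and 1 fallen (adjusted p = 4.96e-16) and NF-kB targets 8 risen and 3 fallen (adjusted p = 9.15e-09). FOXO targets had 10 and 3 (adjusted p = 0.000335), hypoxia targets 10 and 0 (adjusted p = 4.79e-10) and metallothioneins and zinc export 4 and 0 (adjusted p = 0.000192). NRF2 targets had 13 risen (14 adjusted over the list alone) and 4 fallen (adjusted p = 0.0308, but adjusted p = 0.161 with an estimated correlation and 0.0649 without WT PBS replicate 3). Peroxide and thioredoxin enzymes had 13 risen and 1 fallen (adjusted p = 6.25e-05), with SOD1 at 0.46 ± 0.06 and PRDX1 at 0.40 ± 0.05. All 24 ribosomal protein genes rose, RPL30 by 0.48 ± 0.05 (adjusted p = 4.8e-15), with a median of 0.44, or 0.18 relative to the length trend given below. Cholesterol synthesis genes fell in 9 of 15 cases (1 risen adjusted over the list alone), among them HMGCR (-0.69 ± 0.07) and HMGCS1 (-0.66 ± 0.10; adjusted p = 0.000757, but adjusted p = 0.0554 with an estimated correlation). The 75 µM dose changed 2536 genes upward and 2842 downward in WT (949 and 4665 with TPM).

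Fold changes after H2O2 varied with transcript length, taken from the longest annotated transcript of each gene, which need not be the one expressed. Across 10745 genes, which are not independent replicates, the rank correlation of log2 fold change with transcript length was -0.52 at 50 µM and -0.62 at 75 µM in WT. It was -0.60 at both doses with J14, and -0.13 at 50 µM and -0.46 at 75 µM in the SRXN1 line. Of 5 classes of genes by length, that with the shortest transcripts had a median of 0.31 and that with the longest -0.38 in WT at 75 µM.

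**Figure D3:**
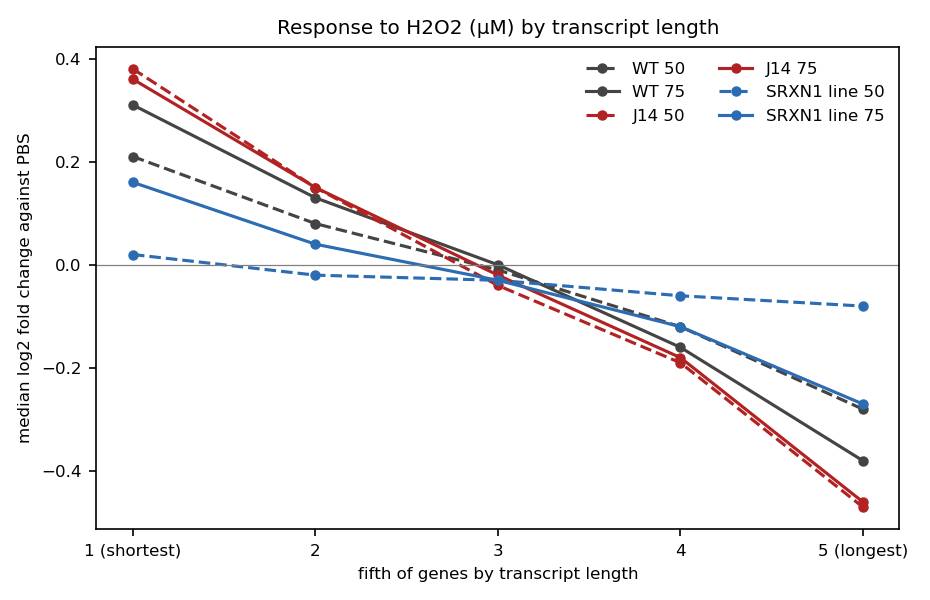
Median log2 fold change against PBS (y axis) of genes in 5 classes of transcript length (x axis, shortest to longest), for WT (grey), J14 (red) and the SRXN1 line (blue) at 50 µM (dashed) and 75 µM (solid) H2O2. In WT at 75 µM the medians ran from 0.31 in the shortest class to -0.38 in the longest, and in the SRXN1 line at 50 µM from 0.02 to -0.08.

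Between the doses in WT, p53 targets were lower at 75 than at 50 µM: MDM2 by -1.42 ± 0.07, CDKN1A by -1.59 ± 0.09, BTG2 by -1.12 ± 0.08, GDF15 by -0.91 ± 0.17, SESN1 by -1.54 ± 0.10, TP53INP1 by -1.71 ± 0.12 and the death receptor FAS by -2.01 ± 0.16. SERPINB5, which is not on the list of p53 targets, stood at -2.05 ± 0.23. Of 30 p53 targets 23 fell and 0 rose (26 adjusted over the list alone), with a median of -0.69 (camera, adjusted p = 2.61e-110). SLC7A11 (-1.55 ± 0.08) and HMOX1 (-1.33 ± 0.12) fell with 4 more of 25 NRF2 targets (7 fell and 1 rose adjusted over the list alone; adjusted p = 4.58e-07). SRXN1 fell by 0.38 ± 0.05. SESN2 (-1.39 ± 0.08) and CHAC1 (-1.63 ± 0.28) were among 8 of 22 fallen genes of the integrated stress response (9 adjusted over the list alone; adjusted p = 1.68e-12). MT1F (-1.38 ± 0.20) and SLC30A1 (-0.96 ± 0.09) were among 3 fallen of 4 genes of metallothioneins and zinc export (4 adjusted over the list alone; adjusted p = 1.5e-12). FOXO targets had 1 risen and 4 fallen (2 and 5 adjusted over the list alone; adjusted p = 0.0017). FOS was higher at 75 µM, by 0.76 ± 0.10. In all, 51 genes rose and 515 fell with the step. The sum of 566 was 1618 with these 2 groups alone in the fit, of which 602 rose and 1016 fell. It was 1035 with a GC correction, with 218 risen and 817 fallen, and 352 without WT 75 µM replicate 3. The small share of rises thus depended on the setting.

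With J14 at 50 µM, immediate early and p53 genes rose, and SLC7A11 and several chaperone genes fell. FOS reached 6.18 ± 0.14, FOSB 6.06 ± 0.28, EGR1 3.56 ± 0.11, CXCL8 4.97 ± 0.54, TNFAIP3 3.07 ± 0.12, ADM 4.30 ± 0.23 and RASD1, a RAS-related GTPase gene, 4.46 ± 0.25. CDKN1A (1.73 ± 0.09), GADD45A (2.75 ± 0.11), BTG2 (2.50 ± 0.09) and MDM2 (0.36 ± 0.07; 0.12 with TPM, adjusted p = 0.214) rose. HMOX1 rose by 1.07 ± 0.12 and the quinone reductase NQO1 by 0.37 ± 0.04, while SLC7A11 fell by 1.04 ± 0.08. ATF3 (3.85 ± 0.14) and SESN2 (1.35 ± 0.08) rose, and CHAC1 stood at 0.29 ± 0.29 (adjusted p = 0.438). ISG15 (1.20 ± 0.24) and IGFBP4 (1.02 ± 0.10) rose, whereas ZNF14 (-2.06 ± 0.32), BSN (-1.94 ± 0.32), the kinetochore gene CENPE (-1.09 ± 0.10), FOXO1 (-0.73 ± 0.15) and HMGCR (-0.69 ± 0.07) fell.

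Of the lists, p53 targets had 20 risen and 1 fallen with J14 at 50 µM (median 0.44; camera, adjusted p = 2.36e-11), immediate early genes 24 and 0 (24 and 1 adjusted over the list alone; median 1.70, adjusted p = 2.87e-63). The integrated stress response had 12 and 1 (adjusted p = 1.96e-09). NF-kB targets had 8 and 1 (10 and 1 adjusted over the list alone; adjusted p = 1.56e-08) and hypoxia targets 8 and 1 (adjusted p = 1.61e-08). Metallothioneins and zinc export had 4 and 0 (adjusted p = 5.88e-06), with MT1F at 2.62 ± 0.23, and ribosomal proteins 23 and 0 (adjusted p = 5.59e-14; median 0.55, or 0.20 relative to the length trend), with RPS24 at 0.64 ± 0.05. FOXO targets had 7 and 4, with a median of 0.18 that turned to -0.14 under TPM (adjusted p = 0.00561). NRF2 targets had 17 and 4 (adjusted p = 0.00321, but adjusted p = 0.0611 with an estimated correlation). Peroxide and thioredoxin enzymes had 12 and 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000907, but adjusted p = 0.0653 with an estimated correlation). FTH1 rose by 0.59 ± 0.06. Heat shock genes had 4 risen and 9 fallen (10 adjusted over the list alone; adjusted p = 0.00894, but adjusted p = 0.0537 with an estimated correlation and 0.078 with these 2 groups alone in the fit). HSPA1A, whose reads are shared with the near-identical HSPA1B, fell by 0.56 ± 0.05 and HSPH1 by 0.81 ± 0.07. The endoplasmic reticulum genes SEL1L (-0.76 ± 0.07) and DNAJC3 (-0.82 ± 0.10) also fell. J14 at 50 µM gave 3401 risen and 3456 fallen genes (1701 and 5406 with TPM). The sum was 6857, and 4245 with these 2 groups alone in the fit.

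At 75 µM with J14, FOS (6.48 ± 0.14), EGR1 (3.73 ± 0.11), CXCL8 (5.14 ± 0.54) and ATF3 (3.71 ± 0.14) were far above PBS. CDKN1A rose by 1.32 ± 0.09, BTG2 by 2.16 ± 0.08 and HMOX1 by 0.61 ± 0.12, while SLC7A11 (-1.45 ± 0.08), HSPA1A (-0.61 ± 0.05), ZNF708 (-2.54 ± 0.32) and HEG1 (-2.12 ± 0.25) fell. MDM2 stood at 0.11 ± 0.07 (adjusted p = 0.183), but at 0.20 without J14 PBS replicate 3 (adjusted p = 0.0022) and at 0.37 with a GC correction (adjusted p = 2.46e-09). Here 17 p53 targets rose and 2 fell (18 and 3 adjusted over the list alone; median 0.35; camera, adjusted p = 7.14e-07). Of 25 immediate early genes 24 rose and 1 fell (adjusted p = 1.57e-69), and the integrated stress response had 12 and 1 (adjusted p = 4.13e-08). NF-kB targets had 9 and 1 (9 and 2 adjusted over the list alone; adjusted p = 2.3e-09), hypoxia targets 8 and 0 (9 adjusted over the list alone; adjusted p = 3.86e-07) and metallothioneins and zinc export 4 and 0 (adjusted p = 0.00105). Ribosomal proteins had 23 and 0 (median 0.48, or 0.19 relative to the length trend; adjusted p = 2.92e-12) and FOXO targets 7 and 4, with a median of 0.00, or -0.17 under TPM (adjusted p = 0.017). The counts were 3362 up and 3429 down (1655 and 5181 with TPM), 6791 in all, against 3856 with these 2 groups alone in the fit.

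From 50 to 75 µM with J14, SESN1 alone passed the threshold (-0.55 ± 0.10, adjusted p = 0.0239), and 0 genes rose in edgeR's test. That call ended without J14 50 µM replicate 1, 2 or 3 (adjusted p = 0.348, 0.119 and 0.0622) and without J14 75 µM replicate 1 or 3 (0.0981 and 0.334). At an unadjusted p below 0.05 there were 649 genes, and DESeq2 called 6. CDKN1A stood at -0.41 ± 0.08 (adjusted p = 0.144), MDM2 at -0.24 ± 0.07 (adjusted p = 0.664), MT1F at -0.81 ± 0.20 (adjusted p = 0.409) and FOS at 0.30 ± 0.09 (adjusted p = 0.833). With these 2 groups alone in the fit CDKN1A (adjusted p = 4.16e-08), MDM2 (0.0019) and FOS (0.00632) were called, and with the GC correction CDKN1A (1.25e-06) and MDM2 (0.00348). As a list, the p53 targets were lower (median -0.13, 0 risen and 1 fallen, 7 fallen adjusted over the list alone; camera, adjusted p = 5.41e-12). So were metallothioneins and zinc export (median -0.34, 0 and 0, 3 fallen adjusted over the list alone; adjusted p = 1.34e-06). The step differed between J14 and WT in 105 genes that were higher and 6 that were lower in J14 relative to WT, a contrast added after the data were seen.

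In the SRXN1 line at 50 µM, all 30 p53 targets rose, with a median of 1.49 (camera, adjusted p = 9.97e-148). CDKN1A rose by 3.55 ± 0.09, MDM2 by 2.24 ± 0.07, BTG2 by 2.71 ± 0.08 and GDF15 by 2.48 ± 0.18. GADD45A, which is not on that list, rose by 3.72 ± 0.11. Of 25 NRF2 targets 19 rose and 0 fell (21 adjusted over the list alone; median 0.37, adjusted p = 7.32e-30). HMOX1 rose by 3.35 ± 0.13, SLC7A11 by 1.95 ± 0.08, GCLC by 1.28 ± 0.08, GCLM by 0.98 ± 0.07 and thioredoxin reductase TXNRD1 by 0.56 ± 0.04. ATF3 (4.41 ± 0.14), CHAC1 (4.31 ± 0.31), SESN2 (3.38 ± 0.09) and asparagine synthetase ASNS (1.31 ± 0.07) were among 20 risen genes of the integrated stress response, where 1 fell (21 and 1 adjusted over the list alone; adjusted p = 3.41e-63). ACTA2 (3.85 ± 0.44) and SERPINE1 (3.76 ± 0.43), genes of smooth muscle actin and a plasminogen activator inhibitor, were among the largest rises, and MEIS1 (-1.67 ± 0.35) and NXPH1 (-1.67 ± 0.43) among the largest falls. FOS (2.09 ± 0.15), EGR1 (1.22 ± 0.10), MAFF (2.37 ± 0.12), CXCL8 (4.14 ± 0.86) and ICAM1 (1.40 ± 0.18) rose. CXCL8 stayed low and varied between libraries, at 2.01 CPM in replicate 1 and 0.54 in replicate 2, against 7.10 to 8.62 with J14 at 50 µM.

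Mitotic, chaperone and luminal genes fell in the SRXN1 line at 50 µM. Of 18 G2/M genes 16 fell and 0 rose (17 adjusted over the list alone; median -0.57; camera, adjusted p = 3.8e-21). Among them were the kinases AURKA (-0.86 ± 0.06) and PLK1 (-0.74 ± 0.06) and CDC20 (-0.61 ± 0.06). Of 16 heat shock genes 12 fell and 0 rose (adjusted p = 7.36e-15), HSPA1A by -1.23 ± 0.06 and HSPA8 by -1.10 ± 0.07. Luminal identity genes had 10 fallen and 1 risen of 14 (3 risen adjusted over the list alone; adjusted p = 2.29e-08). The estrogen receptor gene ESR1 stood at -0.84 ± 0.05, XBP1 at -0.74 ± 0.05 and GATA3 at -0.59 ± 0.06. Estrogen response genes had 7 fallen and 1 risen of 17 (10 fallen adjusted over the list alone; adjusted p = 0.000199), with cyclin D1, CCND1, at -0.61 ± 0.05. G1/S genes had 9 fallen, such as RRM2 (-0.41 ± 0.06), and 2 risen (adjusted p = 0.00407, but adjusted p = 0.0634 with an estimated correlation). Immediate early genes had 18 risen and 0 fallen (adjusted p = 2.58e-36) and NF-kB targets 11 and 0 (adjusted p = 1.76e-08). Hypoxia targets had 8 and 0 (9 adjusted over the list alone; adjusted p = 2.32e-13) and metallothioneins and zinc export 4 and 0 (adjusted p = 1.25e-11), with MT1F at 1.79 ± 0.22. FOXO targets had 10 risen and 2 fallen (adjusted p = 2.07e-09). In total 1486 genes rose and 1593 fell.

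At 75 µM in the SRXN1 line, both the immediate early and the p53 genes were high. FOS rose by 4.70 ± 0.13, EGR4 by 6.48 ± 0.57, CXCL8 by 7.38 ± 0.68, TNFAIP3 by 3.99 ± 0.12 and ICAM1 by 2.21 ± 0.18. So did CDKN1A (3.14 ± 0.09), MDM2 (1.79 ± 0.07), GADD45A (3.92 ± 0.11), PIK3IP1 (2.84 ± 0.41), HMOX1 (2.68 ± 0.13), SLC7A11 (0.79 ± 0.08), ATF3 (5.18 ± 0.14), ADM (4.03 ± 0.20) and MT2A (1.73 ± 0.17), while CENPF (-0.87 ± 0.09) and ZNF708 (-1.21 ± 0.31) fell. Here 29 p53 targets rose and 0 fell (median 1.33; camera, adjusted p = 3.52e-94). Immediate early genes had 23 and 0 (median 1.82, adjusted p = 7.59e-98), NF-kB targets 13 and 0 (adjusted p = 5.56e-24) and the integrated stress response 18 and 0 (adjusted p = 3.84e-39). Hypoxia targets had 9 and 0 (10 adjusted over the list alone; adjusted p = 3.5e-19) and metallothioneins and zinc export 4 and 0 (adjusted p = 4.29e-13). NRF2 targets had 19 risen and 1 fallen (20 and 2 adjusted over the list alone; adjusted p = 5.02e-10), FOXO targets 9 and 2 (10 and 2 adjusted over the list alone; adjusted p = 3.68e-09) and heat shock genes 0 and 7 (adjusted p = 0.00293). A further 6 lists were called with the preset correlation only. There were 1846 genes up and 2337 down (1090 and 3419 with TPM).

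Between the doses in the SRXN1 line, immediate early and NF-kB genes were higher at 75 than at 50 µM, with FOS at 2.61 ± 0.11, FOSB at 2.70 ± 0.19, EGR1 at 1.70 ± 0.10, CXCL8 at 3.25 ± 0.43, TNFAIP3 at 2.56 ± 0.11 and NFKBIA at 0.89 ± 0.06. The hypoxia target ADM stood at 1.91 ± 0.17. Immediate early genes had 19 risen and 1 fallen (22 and 1 adjusted over the list alone; camera, adjusted p = 1.46e-62) and NF-kB targets 7 and 0 (9 adjusted over the list alone; adjusted p = 1.32e-17). Heat shock genes had 6 and 0 (adjusted p = 4.76e-10), with HSPA1A at 0.79 ± 0.05 and DNAJB1 at 0.38 ± 0.06. HSPA6, which is not on that list, stood at 1.93 ± 0.33. G2/M genes had 9 and 0 (12 adjusted over the list alone; adjusted p = 3.2e-10), with AURKA at 0.60 ± 0.06. Luminal genes had 7 and 0 (7 and 1 adjusted over the list alone; adjusted p = 2.97e-05), with ESR1 at 0.36 ± 0.05 and KRT18 at 0.39 ± 0.05. Ribosomal proteins had 11 and 0 (16 adjusted over the list alone; median 0.20, beside 0.14 for the class of shortest transcripts; adjusted p = 6.32e-09) and hypoxia targets 3 and 0 (adjusted p = 4.58e-05). NRF2 targets fell in 9 of 25 cases and rose in 0 (15 fell adjusted over the list alone; adjusted p = 2.9e-10). SLC7A11 stood at -1.16 ± 0.08, HMOX1 at -0.66 ± 0.12, TXNRD1 at -0.42 ± 0.04 and SRXN1 at -0.40 ± 0.05. Of the p53 targets 9 fell and 1, SERTAD1 (0.89 ± 0.17), rose (13 and 1 adjusted over the list alone; median -0.21, adjusted p = 1.43e-05). MDM2 fell by 0.46 ± 0.07, CDKN1A by 0.41 ± 0.08 and VLDLR, a lipoprotein receptor gene, by 1.0 ± 0.24. The step changed 606 genes upward and 1005 downward (281 and 1939 with TPM). The sum was 1611, or 3103 with these 2 groups alone in the fit, 1010 without 50 µM replicate 3 and 995 without 75 µM replicate 2. It differed from that of WT in 147 genes that were higher and 32 that were lower relative to WT.

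J14-treated cells and the SRXN1 line were compared directly at 50 µM, the arms that move sulfiredoxin in opposite directions by their labels. J14 was lower for SRXN1 (-0.87 ± 0.05), SLC7A11 (-2.36 ± 0.08), TXNRD1 (-1.15 ± 0.04), HMOX1 (-1.95 ± 0.12), GCLC (-1.30 ± 0.08), CDKN1A (-1.65 ± 0.09), MDM2 (-1.44 ± 0.07), PPM1D (-1.08 ± 0.06) and CHAC1 (-2.74 ± 0.27). It was higher for FOS (3.53 ± 0.11), EGR1 (1.69 ± 0.10), JUN (1.31 ± 0.07), HSPA1A (1.66 ± 0.06), AURKA (1.37 ± 0.06), PLK1 (1.21 ± 0.06), ESR1 (0.87 ± 0.05), KRT18 (0.66 ± 0.05) and the estrogen-regulated genes TFF1 (1.21 ± 0.06) and GREB1 (0.96 ± 0.07). MALL (-3.49 ± 0.11) and HOXB9 (-2.47 ± 0.28) were among the largest differences, and both also differed between the line and WT in PBS. In list terms 27 p53 targets were lower and 1 higher in J14 (28 and 1 adjusted over the list alone; camera, adjusted p = 7.41e-27), and 15 NRF2 targets lower and 4 higher (adjusted p = 9.99e-10). Also lower were 11 genes of the integrated stress response, with 3 higher (12 and 3 adjusted over the list alone; adjusted p = 5.12e-05) and 10 of 15 cholesterol synthesis genes, with 0 higher (adjusted p = 2.93e-05), HMGCR by -0.77 ± 0.07. Higher in J14 were 18 of 18 G2/M genes (adjusted p = 1.95e-22), 19 immediate early genes with 1 lower (20 and 1 adjusted over the list alone; adjusted p = 8.71e-17) and 12 heat shock genes with 1 lower (12 and 2 adjusted over the list alone; adjusted p = 6.62e-14). So were 10 estrogen response genes with 2 lower (adjusted p = 1.1e-05) and 9 luminal genes with 4 lower (adjusted p = 0.000277). The comparison called 2838 genes up and 2863 down (1587 and 3902 with TPM), and it holds any difference between the backgrounds before H2O2.

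J14 itself, against WT in PBS, was accompanied by higher chaperone genes. HSPA1A (0.84 ± 0.05) and HSPA1B (0.81 ± 0.06), which share reads, HSPH1 (0.54 ± 0.07) and the endoplasmic reticulum chaperone HSPA5 (0.41 ± 0.05) rose, as did SLC7A11 (0.82 ± 0.08), HMOX1 (0.77 ± 0.13) and CHAC1 (1.65 ± 0.34; adjusted p = 0.0552 without WT PBS replicate 3). The retinol-metabolising DHRS3 (-2.14 ± 0.20), the squalene epoxidase gene SQLE (-0.29 ± 0.06) and FOS (-0.93 ± 0.20) fell, and SRXN1 stood at 0.08 ± 0.05 (adjusted p = 0.359). Heat shock genes had 10 risen and 0 fallen (11 and 2 adjusted over the list alone; camera, adjusted p = 4.78e-13) and unfolded protein response genes 6 and 0 (10 adjusted over the list alone; adjusted p = 1.4e-07). Cholesterol synthesis genes had 0 and 7 (8 adjusted over the list alone; adjusted p = 1.09e-05), estrogen response genes 1 and 5 (1 and 8 adjusted over the list alone; adjusted p = 0.000244) and luminal genes 0 and 5 (9 adjusted over the list alone; adjusted p = 1.61e-07). The integrated stress response had 8 and 1 (9 and 2 adjusted over the list alone; adjusted p = 0.000172, but adjusted p = 0.0727 with an estimated correlation). There were 513 risen and 385 fallen genes (710 and 269 with TPM), and fewer risen than fallen with a GC correction (203 and 345) or without a filter on low counts (344 and 410). With these 2 groups alone in the fit, 2 genes were called. The sum of 898 was 183 without WT PBS replicate 3, 299 without WT PBS replicate 2, 335 without J14 PBS replicate 3 and 3048 without J14 PBS replicate 1. Without J14 PBS replicate 3 and WT PBS replicate 1, chosen after the data were seen, it was 551. Fold changes against PBS with J14 start from these levels.

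In PBS the SRXN1 line differed from WT in genes of several kinds. MALL (2.32 ± 0.10), the chromatin regulator SATB2 (2.50 ± 0.24), HOXB9 (1.93 ± 0.30), ADM (2.07 ± 0.32), TXNRD1 (0.52 ± 0.04) and the sterol genes INSIG1 (0.49 ± 0.07) and SQLE (0.42 ± 0.06) were higher in the line. DIO2 (-5.96 ± 0.44), PSTPIP2 (-5.79 ± 0.48), the small heat shock protein HSPB8 (-2.84 ± 0.13), the phosphatase DUSP4 (-1.70 ± 0.07), MT2A (-1.41 ± 0.17), ferritin light chain FTL (-1.27 ± 0.08, a gene with many pseudogene copies), TFF1 (-0.76 ± 0.06), GREB1 (-0.62 ± 0.07), TXNIP (-0.54 ± 0.07), the lipid peroxidase GPX4 (-0.45 ± 0.06) and AURKA (-0.38 ± 0.06) were lower. Of the lists, 12 of 18 G2/M genes were lower (14 adjusted over the list alone; camera, adjusted p = 0.000333, but adjusted p = 0.33 with an estimated correlation). Cholesterol synthesis genes had 7 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00108, but adjusted p = 0.179 with an estimated correlation), and estrogen response genes 1 higher and 7 lower (3 and 7 adjusted over the list alone; adjusted p = 0.00702, but adjusted p = 0.179 with an estimated correlation). The line had 1159 genes above and 1260 below WT, and 1802 and 1582 with a GC correction.

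Responses to 50 µM were compared between J14 and WT by tests of the difference. MDM2 (-1.20 ± 0.10), CDKN1A (-1.15 ± 0.12), SLC7A11 (-1.63 ± 0.11), HMOX1 (-1.25 ± 0.18), CHAC1 (-2.96 ± 0.43) and SESN2 (-1.21 ± 0.12) had lower responses with J14 than in WT, and FOS (1.58 ± 0.22) a higher one. HSPA1A (-0.48 ± 0.08) and HSPA5 (-0.39 ± 0.07; adjusted p = 0.0671 with these groups alone in the fit) also had lower responses. Of the 10 genes named here, 8 differed between J14 and WT already in PBS, in the direction opposite to the difference of responses. Among them SLC7A11, HMOX1, CHAC1, HSPA1A and HSPA5 were higher and FOS lower there. The same held for 430 of all 787 genes called, so these tests alone do not separate a changed response to H2O2 from another starting level. Levels at 50 µM differed by gene. SLC7A11 stood at 339.2 to 444.4 CPM with J14 and 205 to 218.8 in WT in PBS, but at 174.3 to 190.6 and 305.4 to 340.8 at 50 µM. HMOX1 and CHAC1 likewise turned from higher to lower in all libraries, and FOS from lower to higher. CDKN1A overlapped in PBS and was lower with J14 at 50 µM. HSPA1A stayed higher with J14 in all libraries. Of the lists that follow, all but the p53 targets were called the opposite way between J14 and WT in PBS, the integrated stress response with the preset correlation only. Of 30 p53 targets 17 had lower and 0 higher responses (18 lower adjusted over the list alone; median -0.51; camera, adjusted p = 3.23e-30). Lower responses were also called for the integrated stress response (7 lower, 1 higher; 12 and 2 adjusted over the list alone; adjusted p = 4.37e-10), heat shock genes (6 and 0; 9 and 1 adjusted over the list alone; adjusted p = 0.000235) and the unfolded protein response (6 and 0; adjusted p = 0.000235). Higher ones were called for estrogen response genes (5 higher, 0 lower; 8 and 1 adjusted over the list alone; adjusted p = 0.000342) and luminal genes (4 and 0; 8 adjusted over the list alone; adjusted p = 7.54e-06). SRXN1 stood at -0.28 ± 0.08 (adjusted p = 0.0258), a call that ended without J14 50 µM replicate 3 (adjusted p = 0.0736), WT 50 µM replicate 1 (0.0512) or 2 (0.0524) or WT PBS replicate 3 (0.0668), without a filter on low counts (0.0614) and with these groups alone in the fit (0.166). There were 266 genes with a higher and 521 with a lower response (145 and 970 with TPM). The sum was 787, against 134 with these 4 groups alone in the fit. It was 1914 without J14 PBS replicate 1, 505 without J14 50 µM replicate 3, 424 without WT 50 µM replicate 1, and 465 and 418 without WT PBS replicate 2 and 3.

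At 75 µM, 29 genes had a higher and 7 a lower response with J14 than in WT, 36 in all, with 1569 at an unadjusted p below 0.05. FOS (1.13 ± 0.22), BTG2 (0.64 ± 0.12) and DHRS3 (1.85 ± 0.27) were higher, and HSPA1A (-0.66 ± 0.08) and HSPA5 (-0.39 ± 0.07) lower. With these 4 groups alone in the fit FOS (adjusted p = 0.0543), BTG2 (0.379), DHRS3 (0.109) and HSPA5 (0.411) were not called. All 5 genes named differed the opposite way between J14 and WT in PBS, as did 35 of the 36 genes, and the 5 lists that follow were called the opposite way there. Heat shock genes had 3 lower and 0 higher responses (10 adjusted over the list alone; median -0.25; camera, adjusted p = 9.43e-09) and unfolded protein response genes 1 and 0 (3 adjusted over the list alone; median -0.19, adjusted p = 1.28e-05). Cholesterol synthesis (median 0.23, 0 genes called, 5 higher adjusted over the list alone; adjusted p = 2.32e-06), estrogen response (median 0.27, 1 higher, 6 and 1 adjusted over the list alone; adjusted p = 0.000229) and luminal genes (median 0.17, 1 higher, 4 adjusted over the list alone; adjusted p = 0.000116) had higher ones. The count of 36 was 2, both lower, with these 4 groups alone in the fit, 83 with a GC correction, 81 with DESeq2, 336 without J14 PBS replicate 1, 62 without J14 PBS replicate 3, and between 15 and 22 without any one library of J14 or WT at 75 µM or WT PBS replicate 2 or 3.

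The SRXN1 line had higher p53 and NRF2 responses than WT at both doses. At 50 µM the difference was 0.69 ± 0.10 for MDM2, 1.39 ± 0.24 for FAS, 0.67 ± 0.12 for CDKN1A, 1.36 ± 0.11 for SLC7A11, 0.41 ± 0.06 for TXNRD1, 1.03 ± 0.18 for HMOX1, 2.06 ± 0.34 for HEG1 and 0.53 ± 0.08 for SRXN1. It was -2.51 ± 0.22 for FOS, -2.25 ± 0.14 for EGR1, -1.0 ± 0.10 for JUN, -0.93 ± 0.08 for NFKBIA, -1.15 ± 0.08 for HSPA1A, -0.80 ± 0.09 for AURKA and -0.72 ± 0.08 for PLK1. Of the p53 targets 15 had higher and 1 lower responses (19 and 1 adjusted over the list alone; median 0.42; camera, adjusted p = 9.97e-13), and of the NRF2 targets 9 and 0 (12 adjusted over the list alone; median 0.19, adjusted p = 2.3e-09). Immediate early genes had 15 lower and 1 higher (19 and 1 adjusted over the list alone; median -0.71, adjusted p = 6.49e-25) and G2/M genes 10 and 0 (13 adjusted over the list alone; adjusted p = 2.3e-13). Heat shock genes had 6 and 0 (9 adjusted over the list alone; adjusted p = 2.88e-14) and luminal genes 5 and 0 (9 and 1 adjusted over the list alone; adjusted p = 1.05e-05). The test called 836 genes higher and 593 lower (1488 and 274 with TPM). The sum was 1429, or 2452 with these 4 groups alone in the fit (1495 higher and 957 lower) and 2161 with a GC correction (1101 and 1060). Of these genes 297 differed between the line and WT in PBS in the opposite direction and 167 in the same one.

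At 75 µM the difference between the line and WT was 1.65 ± 0.10 for MDM2, 1.85 ± 0.12 for CDKN1A, 2.95 ± 0.24 for FAS, 1.91 ± 0.14 for SESN1, and 1.75 ± 0.11 for SLC7A11. It was 1.70 ± 0.18 for HMOX1, 1.87 ± 0.12 for SESN2, 2.84 ± 0.36 for SERPINB5, 1.35 ± 0.25 for ICAM1, 1.93 ± 0.37 for BIRC3 and 0.51 ± 0.08 for SRXN1. HSPA1A (-0.48 ± 0.08) and AURKA (-0.45 ± 0.09) had lower responses. Of the p53 targets 21 had higher and 0 lower responses (26 adjusted over the list alone; median 0.99; camera, adjusted p = 2.98e-74). NRF2 targets had 7 and 0 (adjusted p = 5.93e-06) and the integrated stress response 7 and 0 (8 adjusted over the list alone; adjusted p = 1.19e-07). NF-kB targets had 7 and 0 (8 and 1 adjusted over the list alone; adjusted p = 5.4e-06), metallothioneins and zinc export 2 and 0 (3 adjusted over the list alone; adjusted p = 0.000257) and FOXO targets 3 and 1 (5 and 3 adjusted over the list alone; adjusted p = 0.0112). Lower responses were called for G2/M genes (7 lower, 0 higher; 12 adjusted over the list alone; adjusted p = 3.92e-09) and heat shock genes (4 and 0; 5 adjusted over the list alone; adjusted p = 3.97e-05). Here 710 genes were higher and 263 lower (966 and 104 with TPM). The sum was 973, or 1847 with these 4 groups alone in the fit (1097 higher and 750 lower) and 1794 with a GC correction (1035 and 759). In PBS 207 of them differed the opposite way and 87 the same way.

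The authors' deposited tables covered the comparisons at 50 µM. Per the authors' deposited tables, 2007 genes were higher and 2228 lower in WT at 50 µM, 3506 and 3447 with J14, 1591 and 1670 in the SRXN1 line, and 2815 and 2996 in J14 against that line. Across genes, which are not independent replicates, the fold changes of the authors' deposited tables correlated with those above at 0.997 to 0.999.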

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

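The tests of the 3 patterns below, and the splits of the libraries for WT at 50 µM against PBS, the dose step in WT and the responses to 50 µM, the grouping of splits by whether they mix both treatments, and the counts of genes that differ in PBS were chosen after the results were seen; the other splits were planned. The results here are differences between the responses of 2 backgrounds that passed a test of the difference itself, as log2 values.

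At 50 µM, the difference from PBS was not the same with J14 as in WT for 787 genes, of which 430 differed the opposite way in PBS. The differences were -1.20 for MDM2, -1.15 for CDKN1A, -1.63 for SLC7A11, -1.25 for HMOX1, -2.96 for CHAC1, -1.21 for SESN2, -0.48 for HSPA1A, -0.39 for HSPA5, -0.28 for SRXN1 and 1.58 for FOS. Medians of lists were -0.51 for p53 targets, -0.23 for heat shock genes, -0.24 for the integrated stress response, -0.14 for the unfolded protein response, 0.29 for estrogen response and 0.24 for luminal genes. All of these lists but the p53 targets were called the opposite way in PBS. With these groups alone in the fit, 1 of 25 splits, the real one, gave 134 genes. The highest other, which keeps one treatment whole, gave 7. For each difference of responses only 25 of the possible splits were drawn, the real one included. The 18 drawn here that mix the backgrounds in both treatments gave at most 0 genes, but they are too few for a share under 0.05. This limit comes from the number drawn and not from the design. Chance thus stays open for this count.

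In the SRXN1 line 1429 genes responded differently to 50 µM. The differences were 0.69 for MDM2, 1.39 for FAS, 0.67 for CDKN1A, 1.36 for SLC7A11, 0.41 for TXNRD1, 1.03 for HMOX1, 0.53 for SRXN1, 2.06 for HEG1, -2.51 for FOS, -2.25 for EGR1, -1.0 for JUN, -0.93 for NFKBIA, -1.15 for HSPA1A, -0.80 for AURKA and -0.72 for PLK1. List medians were 0.42 for p53 targets, 0.19 for NRF2 targets, -0.35 for heat shock genes, -0.71 for immediate early genes, -0.40 for G2/M genes and -0.20 for luminal genes. The splits leave chance open: 2 of 25 gave as many genes, the real one 2452 and the highest other 2819. That other split keeps one treatment whole, so it holds the difference between the backgrounds and does not test chance. The 19 splits drawn that mix the backgrounds in both treatments gave at most 0 genes, but so few drawn splits cannot give a share under 0.05.

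At 75 µM it differed for 36 genes with J14, of which 35 differed the opposite way in PBS. The differences were 1.13 for FOS, 0.64 for BTG2, 1.85 for DHRS3, -0.66 for HSPA1A and -0.39 for HSPA5, with list medians of -0.25 for heat shock genes, -0.19 for the unfolded protein response, 0.23 for cholesterol synthesis, 0.27 for estrogen response and 0.17 for luminal genes. Chance is open for this count as well, as 5 of 25 splits gave as many: the real one gave 2 genes and the highest other, which keeps one treatment whole, 5. The 17 that mix both gave at most 0.

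In the SRXN1 line 973 genes responded differently to 75 µM. The differences were 1.65 for MDM2, 1.85 for CDKN1A, 2.95 for FAS, 1.91 for SESN1, 1.75 for SLC7A11, 1.70 for HMOX1, 0.51 for SRXN1, 1.87 for SESN2, 2.84 for SERPINB5, 1.35 for ICAM1, 1.93 for BIRC3, -0.48 for HSPA1A and -0.45 for AURKA. List medians were 0.99 for p53 targets, 0.12 for NRF2 targets, 0.36 for FOXO targets, -0.17 for heat shock genes, 0.30 for the integrated stress response, 0.78 for NF-kB targets, 0.64 for metallothioneins and zinc export and -0.32 for G2/M genes. Of 25 splits 1 was as large, the real one, with 1847 genes, and the highest other gave 1785. That other split again keeps one treatment whole and so holds the difference between the backgrounds. The 19 drawn that mix both gave at most 0 genes, but so few drawn splits cannot give a share under 0.05. The splits thus leave chance open here too. The step from 50 to 75 µM differed from that of WT in 111 genes with J14 and in 179 genes in the SRXN1 line.

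Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. With the compared groups alone in the fit, the real split and the highest other gave 4621 and 0 genes for WT at 50 µM, 4245 and 0 for J14 at 50 µM, 4560 and 0 for the SRXN1 line at 50 µM, 5853 and 0 for WT at 75 µM, 3856 and 0 for J14 at 75 µM, and 5766 and 0 for the SRXN1 line at 75 µM. For the dose step they gave 1618 and 0 in WT, 18 and 1 with J14 and 3103 and 0 in the SRXN1 line. They gave 6861 and 0 for J14 against the SRXN1 line at 50 µM, 2 and 0 for J14 against WT in PBS, and 3043 and 1 for the SRXN1 line against WT in PBS.

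The p53 targets were lower at 75 than at 50 µM in WT, with a median of -0.69 over 30 genes. A GC correction left the median at -0.69, and relative to the trend of all genes with transcript length it was -0.65, which argues against GC content or length as the whole source. An exchange of the WT libraries of both doses would turn the sign of the step, but of 292 genes called in the steps of WT and of the SRXN1 line 282, or 96.6%, had the same sign, where independence gives 59 shared genes. A weaker p53 programme at the higher dose may thus be biological, a hypothesis found and tested on the same data. Loss of the most damaged cells and a slower or earlier response were not tested, since RNA was taken at 1 time.

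Many genes differed between the SRXN1 line and WT in PBS, while SRXN1 itself stood 0.15 log2 above WT. Of 2419 called genes 2335 were called in the same direction after the GC correction, which argues against GC content as the source. Growth of the line from one or few cells stays open: 4 genes (LDHB, DPYD, LHFPL6 and CCN5, chosen after their values were seen) were under 0.5 CPM in all 9 libraries of the line and above 2 CPM in all others. WT and J14 are the same cells, so the design has no second line in which to look for such losses. LDHB (chromosome 12, 21635342 to 21657842) had 0 counts in every library of the line and 985 to 1604 in each other library, at least 390-fold lower in PBS with a floor of 3 counts per library. Whether the construct contributes to the differences cannot be told apart from such growth, since there is 1 line and the counts may leave out its transcript.

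Genes with longer transcripts had lower fold changes after H2O2. The rank correlation across genes in WT at 75 µM was -0.62, and -0.54 after the GC correction, which argues against GC content as the whole source. Breakage of RNA in the treated cells or extracts could give it, and so could a faster loss of long messages in the cells: the correlation with transcript length given gene span was -0.46, and the data hold no measure of RNA integrity to separate them. Slower transcription over long genes stays open as well, with a correlation with gene span given transcript length of -0.25 that was -0.13 after the GC correction. In the SRXN1 line at 50 µM the correlation with length was -0.13, so the trend differed between treated groups.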

How the results depend on the processing

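The GC correction, the removal of J14 PBS replicate 3 and WT PBS replicate 1 together, and the differences of the dose step were chosen after the data were seen; the other alternatives were planned. The naming rule gave 1725 gene results. The text names 295 of them, partly chosen for keeping their call, so shares are given over all that the rule gave. Direction and side of the threshold were kept by 1718 with RLE factors, 1688 without a filter, 1662 of 1671 with the stricter filter, 1702 with the replicate number as a block, 1684 with DESeq2, 1565 of 1724 with the GC correction (4 reversed), 1445 of 1673 with only the compared groups in the fit and 1473 of 1624 with TPM + 1 (7 reversed). Of 158 lists called in 304 tests, 111 were also called with an estimated correlation, 153 with fry, 154 with the GC correction, 153 with only the compared groups and 158 with the replicate number as a block; fry called 42 more. The 47 called with the preset correlation but not with the estimated one are mostly left out of the text. With a fold threshold 100 of the 295 named results were no longer called. Depth limits genes near the filter, and 3 libraries per group limit small changes.

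SRXN1 with J14 reversed with TPM: at 50 µM to -0.04, which was not called, and at 75 µM to -0.15, a called fall, under each of the 3 TPM alternatives; the cause was not tested.

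Counts of called genes moved by over 1.5 times as follows, and unless the alternative itself lowers the count (a fold threshold, fewer samples) the cause was not tested. With an absolute log2 fold change of at least 1 they were 534 for WT, 1097 for J14 and 523 for the SRXN1 line at 50 µM, 663, 1035 and 685 in that order at 75 µM, 57, 0 and 85 for the dose steps, 1106 for J14 against the SRXN1 line, 57 for J14 and 473 for the SRXN1 line against WT in PBS, and for the differences of responses 71 (J14) and 165 (SRXN1 line) at 50 µM and 9 and 207 at 75 µM. With only the compared groups they were 4245 for J14 at 50 µM, 3856 for J14 at 75 µM, 1618, 18 and 3103 for the dose steps in WT, J14 and the SRXN1 line, 2 for J14 against WT in PBS, and 134 and 2452 at 50 µM and 2 and 1847 at 75 µM for the differences of responses. With the GC correction they were 1035 and 6 for the dose steps in WT and J14, 548 for J14 against WT in PBS, 2161 for the response of the SRXN1 line to 50 µM, and 83 and 1794 for the responses of J14 and the line to 75 µM. DESeq2 gave 6 for the dose step with J14 and 81 for the response of J14 to 75 µM. Without a filter on low counts the dose step with J14 gave 3. With TPM + 1 that step gave 0 and the response of J14 to 75 µM 22, with TPM + 0.1 they gave 0 and 22 and the dose step in WT 851, and with TPM + 1 without a filter they gave 0 and 17. With 1 library fewer in J14 PBS and WT PBS the counts were 551 for J14 against WT in PBS, 2290 for the response of the line to 50 µM, and 99 and 1797 for those of J14 and the line to 75 µM.

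Without each library in turn, the lowest and highest counts were 2940 and 3714 for WT, 6115 and 7277 for J14 and 2331 and 2649 for the SRXN1 line at 50 µM, and 4313 and 4915, 5987 and 7183, and 3336 and 3682 at 75 µM. They were 352 (without WT 75 µM replicate 3) and 479 for the dose step in WT, 0 and 1 with J14, and 995 (without the line's 75 µM replicate 2) and 1328 in the SRXN1 line. For J14 against the line they were 4822 and 5056, for J14 against WT in PBS 183 (without WT PBS replicate 3) and 3048 (without J14 PBS replicate 1), and for the line against WT 1691 and 2082. The differences of responses gave 418 (without WT PBS replicate 3) and 1914 (without J14 PBS replicate 1) with J14 and 961 and 1371 in the line at 50 µM, and 15 and 336 (without J14 PBS replicate 1) with J14 and 693 and 910 in the line at 75 µM.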

Other observations

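All tests here were chosen after the results were seen. Zinc finger genes, a class of 393 tested genes whose symbols start with ZNF, had 16 risen and 85 fallen members in WT at 50 µM and 14 and 135 at 75 µM, with medians of -0.19 and -0.33. With J14 they had 35 and 154 at 50 µM and 33 and 169 at 75 µM, with medians of -0.39 and -0.45. In the SRXN1 line they had 41 risen and 17 fallen at 50 µM (median 0.07) and 27 and 57 at 75 µM (median -0.07). The response of the line exceeded that of WT in 30 zinc finger genes at 50 µM and 27 at 75 µM, and fell below it in 0 at either dose, in tests of the difference. In PBS, however, 11 zinc finger genes were higher and 37 lower in the line than in WT, with a median of -0.17. The tests thus do not separate a changed response from another starting level. After the GC correction the medians in WT were -0.17 and -0.32. Relative to the trend of all genes with transcript length the medians were -0.15 and -0.23 in WT, -0.31 and -0.34 with J14, and 0.08 and -0.04 in the SRXN1 line.

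ROBO1, an axon guidance receptor gene on chromosome 3 (78597239 to 79767998), averaged 40.8 CPM in WT and 0.883 CPM in the SRXN1 line in PBS, a ratio of 46.1. DPYD, the enzyme that breaks down pyrimidines, was at least 23.5-fold lower in the line, LHFPL6 at least 63.3-fold and CCN5 at least 36.5-fold, with a floor of 3 counts per library. These genes were chosen after their values were seen.

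In PBS with J14, replicate 3 stood apart along GC content: the deviation from the group mean correlated with it at -0.796 there, 0.73 in replicate 1 and 0.589 in replicate 2. Deviations from a group mean cancel out, so the values of replicates 1 and 2 partly mirror that of replicate 3. The chi-square per degree of freedom was 7.59 between replicates 1 and 2, 57.5 between 1 and 3 and 41.4 between 2 and 3. In WT in PBS the values were -0.476 in replicate 1 and 0.472 in replicate 3. These are correlations across genes, which are not independent replicates.

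A hypothesis is that J14 shifts the response toward that of a higher dose and the SRXN1 line toward that of a lower one. Across genes, the fold changes of J14 at 50 µM correlated at 0.801 with those of WT at 50 µM and at 0.875 with those of WT at 75 µM, a difference of 0.075 (0.063 to 0.099 without any one library, 0.077 with the GC correction). Those of the SRXN1 line at 75 µM correlated at 0.852 with WT at 50 µM and at 0.687 with WT at 75 µM, a difference of -0.165 (-0.178 to -0.153 without any one library, -0.174 with the GC correction). Both are consistent with such a shift. The shared WT PBS libraries enter both correlations of a pair, and the difference between the backgrounds in PBS, the length trend and growth from few cells may contribute, so sulfiredoxin itself is not shown to be the source.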
